A study of Homo sapiens with 9 samples.

How the data were processed

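PANC-1 cells without a guide RNA (WT) and the KDM6A knockout clones KO C22 and KO C28 were sampled with Bru-seq (replicates 1 and 2 of each line) and BruUV-seq (1 library of each line). Per the labels' protocols, cells were labelled with 2 mM bromouridine for 30 min with a chase of 0 h, BruUV-seq cells received 100 J/m2 of UV light before labelling, and bromouridine-containing RNA was captured with an antibody on beads, primed at random and made into strand-specific libraries. Per the submitters' processing notes, base calling used CASAVA 1.8.2 and reads were aligned with Bowtie2 2.3.3 and STAR 2.5.3a and counted with bedtools 2.16.2, with the builds hg38 and GRCh38 named and their roles not stated. The deposited tables, 1 per library, list 57733 genes by versioned Ensembl identifier and symbol and carry no column headers. From the values, the deposited tables give an expected count per gene (estimated reads over the gene body, many of them fractional) and an RPKM, both made by the authors. The release of the gene annotation is not given in the sources used here. Whether counting kept strands apart was judged from the antisense RNA KCNMA1-AS1, whose read density stayed far below that of KCNMA1.

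Counts were taken as deposited, rounded to whole numbers for the tests. Genes enter as the symbol and identifier in the tables, and all coordinates are those of the tables. CPM values are counts over library size, scaled by TMM over all 9 libraries. Estimated reads in genes, in M reads, were 22.4 and 25.7 for Bru-seq WT, 18.3 and 31.1 for KO C22, 15.8 and 5.64 for KO C28, and 22.2, 14.4 and 16.9 for BruUV-seq WT, KO C22 and KO C28. The share of reads outside genes was taken from the library total that the RPKM values imply. Counting intervals cover counting error alone, because reads without molecular identifiers hold PCR copies, and they are exact binomial intervals at 95%. The number of a replicate was not used to pair libraries: residuals of libraries with the same number correlated across genes at 0.435 (WT and KO C22), -0.003 (WT and KO C28) and -0.479 (KO C22 and KO C28).

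The 6 Bru-seq libraries were fitted together with edgeR 4.0.16 (R 4.3.3): filterByExpr, TMM factors, 1 coefficient per line, quasi-likelihood F tests and Benjamini-Hochberg adjustment at 0.05, giving 22827 genes and a common biological coefficient of variation of 79.3%. A fit of all 9 libraries with 1 coefficient per line and 1 for the assay gave 20819 genes and 63.4%. BruUV-seq was compared with Bru-seq in the same 9 libraries with line as a covariate. Standard errors come from the spread the model estimates. Genes changed in both clones had to pass in each with the same sign, and were set beside the product of the separate counts over the number of genes and beside 20 simulated runs in which unchanged clones share the WT libraries. BruUV-seq between lines has 1 library each, so ratios with a prior count of 2 are given without p, for genes with a mean of at least 100 counts where folds are correlated between clones and assays.

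Gene lists, 36 in number, covered among others chemokines, NF-kB, interferon, antigen presentation, KDM6 and Polycomb complexes, HOX, developmental and pancreatic factors, tumour subtypes, epithelial, mesenchymal and matrix genes, TGF-beta, immediate early, YAP, WNT and NOTCH, hypoxia, cholesterol, stress, heat shock and p53 responses, growth and metabolism, and markers of other cells. Of their 1068 symbols 1067 were in the tables. They were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a correlation preset at 0.01, adjusted over the lists of a contrast, with the correlation estimated and with fry as alternatives. Members were also counted after adjusting over the list alone. In BruUV-seq, medians were placed among 10000 random lists of the same size.

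Named genes are KDM6A, CXCL1 and the other CXCR2 ligands, and in each comparison the 10 largest changes up and 10 down among genes that passed (5 up and 5 down for BruUV-seq against Bru-seq). These needed a mean of at least 100 counts in the higher group, both libraries of 1 group above both of the other, and less than 50% of the gene body under a more abundant gene of the same strand, and small RNAs, pseudogenes and antisense symbols were left out. Between lines with both assays the BruUV-seq libraries also had to differ the same way, except for genes changed in both clones. For both clones the smaller of the changes ranked the genes, and up to 4 members per list with the smallest adjusted p were named.

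The tests were tried on simulated counts with the measured depths and spread. Genes given a single-gene change were drawn only from those above a minimum mean count, so the shares found do not cover the least abundant genes tested. For 2-, 4-, 8- and 16-fold changes the Bru-seq test (21271 genes) found 0%, 1.36%, 16.4% and 33.1% in KO C22 with 2 false calls per run and 0%, 4.08%, 15.1% and 31.7% in KO C28 with 3. With both assays (20125 genes) it found 1.33%, 14.3%, 52.9% and 76.2% in KO C22 with 3.33 false calls per run and 0.667%, 16.3%, 56.4% and 71.3% in KO C28 with 4. BruUV-seq against Bru-seq (20124 genes) found 0%, 36%, 69.4% and 78% with 3 false calls. Camera on 21317 genes found the mitosis list shifted by 0.5, 1 and 2 on the log2 scale in 0, 10 and 10 of 10 runs (0, 0 and 7 with an estimated correlation), with 0.1 other lists called per run. The simulated genes varied independently of each other. These runs therefore do not show how many lists would be called falsely where genes vary together.

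Alternatives tried were RLE factors, library totals alone, DESeq2 1.42.0, limma-voom, no filter, a mean of at least 100 counts, replicate number as a block, only genes with under 50% of the body overlapped, removal of the 20 most abundant genes, at least 2-fold, adjusted p below 0.01, only the 4 libraries compared, a prior count of 0.5, and leaving out each library. Added after the data were seen were the fit of both assays, background subtraction (read density in 403 olfactory receptor genes, which these cells hardly transcribe, times gene length), an offset for the trend with gene length, and voom with quality weights. Library totals alone moved the median of all genes by -0.13 in KO C22, 0.39 in KO C28 and 0.51 between the clones in Bru-seq, and by -0.18, 0.19 and 0.37 with both assays. With these shifts, among called lists only the collagen difference between clones with both assays changed sign (median -0.31, 0.11 with library totals). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Signal along genes, exon by exon values and enhancers were not analysed here.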

Results

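Nascent RNA was measured in the pancreatic cancer line PANC-1, in an unedited control line (WT) and in a pair of clones, KO C22 and KO C28, in which CRISPR/Cas9 was aimed at KDM6A. KDM6A (UTX) encodes a histone demethylase that removes a repressive methyl mark laid down by Polycomb complexes. Bru-seq captures RNA made during 30 min with 2 mM bromouridine, and BruUV-seq adds 100 J/m2 of UV light first, so that polymerases stall and signal gathers near the starts of genes. The series holds 2 Bru-seq libraries and 1 BruUV-seq library per line, 9 in all, with 15.8 to 31.1 M estimated reads in genes except for Bru-seq KO C28 replicate 2 (5.64 M) and BruUV-seq KO C22 (14.4 M). Bru-seq KO C28 replicate 2 also had 46.5% of its reads outside genes, against 10.8% to 20.01% in the other Bru-seq libraries, and correlations across genes of 0.649 to 0.793 with the other 8 libraries. Groups, comparisons, gene lists and the Bru-seq test were chosen before the data were examined; the fit that joins both assays, the analyses without Bru-seq KO C28 replicate 2, and the naming of AFAP1-AS1 and MAGI2-AS3 were chosen after the data were seen. The p-values measure only the spread between these samples, since the labels do not say that replicates were separate cultures.

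KDM6A, the gene aimed at (chromosome X, 44873177 to 45112602, plus strand), was transcribed in every library. It stood at 318 and 283 CPM (counts scaled to library size) in WT Bru-seq, 253 and 440 in KO C22, and 324 and 77.7 in KO C28, with 205, 121 and 190 in BruUV-seq of WT, KO C22 and KO C28. In Bru-seq its log2 fold change was 0.24 (SE 0.85) in KO C22 and -0.61 (SE 0.86) in KO C28, with n = 2 libraries per line and edgeR adjusted p of 1 and 0.875. With both assays in 1 fit it was -0.01 (SE 0.57) in KO C22 and -0.35 (SE 0.57) in KO C28. CRISPR lesions are mostly small, and reads summed over a gene body do not show a small lesion, so these values do not test whether functional protein was lost. KDM6B, a paralogue of KDM6A, lay at -1.58 (SE 1.09) and -1.83 (SE 1.10) in KO C22 and KO C28 and did not pass.

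**Figure D1:**
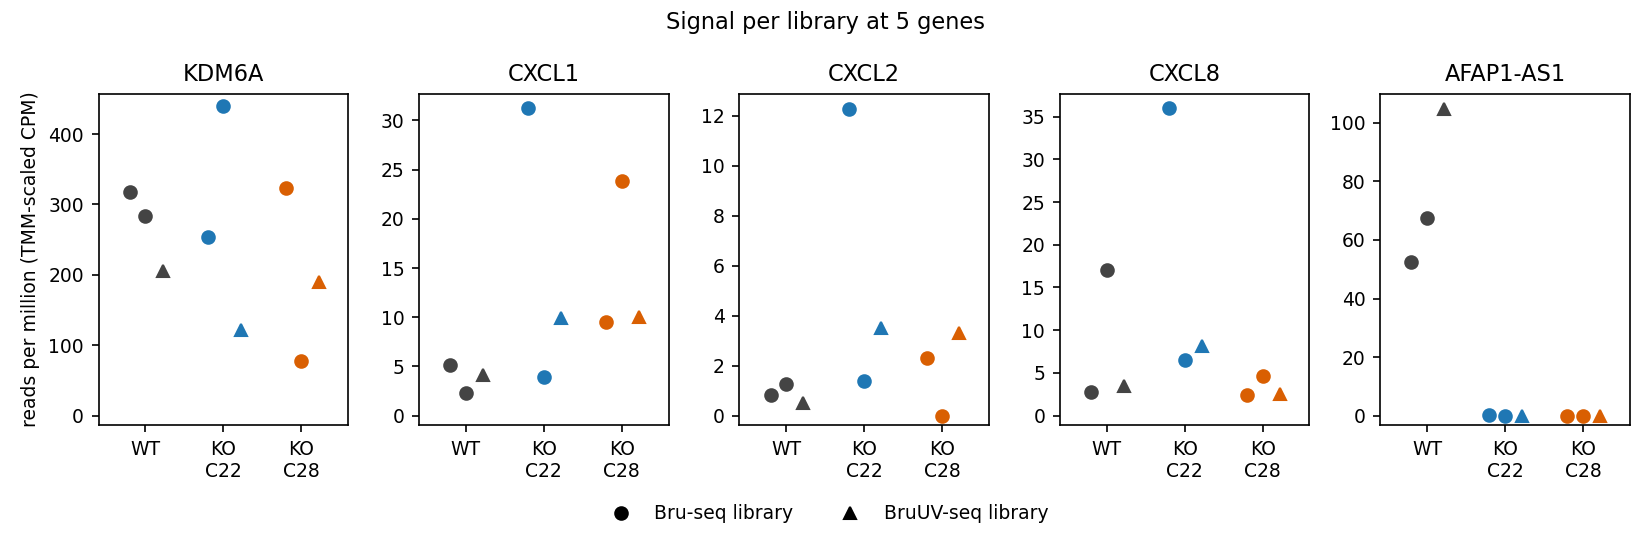
KDM6A, CXCL1, CXCL2, CXCL8 and AFAP1-AS1 in each of the 9 libraries, in CPM. Circles are Bru-seq and triangles are BruUV-seq.

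In KO C22, transcription of the long noncoding RNA AFAP1-AS1 was almost gone. This RNA, antisense to AFAP1 on chromosome 4 (7754090 to 7778928, plus strand) and known for high levels in several cancers, gave 1158 and 1602 reads in WT Bru-seq and 2464 in WT BruUV-seq, against 2, 1 and 0 reads in the same libraries of KO C22. Scaled for library size, WT over KO C22 was a ratio of 1578 (95% counting interval 540 to 7653). It was the only gene of 22827 to pass the edgeR quasi-likelihood test on the Bru-seq libraries (log2 fold change -9.55, SE 1.02, Benjamini-Hochberg adjusted p = 0.0287, n = 2 per line). Unadjusted p below 0.05 was met by 458 genes, where 1141 would be met without any difference. Leaving out Bru-seq WT replicate 2 or KO C28 replicate 1 left 0 genes, and leaving out WT replicate 1, KO C22 replicate 1, KO C22 replicate 2 or KO C28 replicate 2 gave 3, 22, 7 and 4. DESeq2 called 91 genes and limma-voom 0.

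With the BruUV-seq libraries in the same fit (n = 3 libraries per line), 37 of 20819 genes passed in KO C22, 26 higher and 11 lower (41 with an offset for the trend with gene length, 19 higher and 22 lower, 27 of them among the 37, and 6 after background subtraction, 5 higher and 1 lower). LAMB3, a laminin subunit of basement membranes, rose by a log2 fold change of 4.34 (SE 0.45) and stood at 2.72 (SD 0.201), 54.2 (SD 17.5) and 25.2 (SD 6.90) CPM in Bru-seq of WT, KO C22 and KO C28. The extracellular hemicentin HMCN1 rose by 4.73 (SE 0.69), the collagen-binding integrin subunit ITGA11 by 4.55 (SE 0.75) and the secreted proteoglycan SPOCK1 by 4.32 (SE 0.54). HHIP, which binds hedgehog ligands, rose by 6.70 (SE 0.96) from 3, 2 and 3 reads in the WT libraries. The phospholipid phosphatase PLPP4 rose by 4.98 (SE 0.44), SIPA1L2 by 4.57 (SE 0.63), the natriuretic peptide clearance receptor NPR3 by 4.35 (SE 0.59), the semaphorin receptor PLXNA2 by 4.29 (SE 0.64) and SETBP1 by 4.2 (SE 0.65). Adjusted p for these 10 genes ran from 0.00141 (PLPP4) to 0.0419 (ITGA11) in edgeR. The immediate early gene FOS (-4.97, SE 0.77), the ubiquitin ligase gene MID1 (-4.23, SE 0.56) and the gap junction gene GJA1 (-3.75, SE 0.58) fell. So did the fibrillar collagen chain COL5A2 (-2.94, SE 0.38), the phosphatase PTPN13 (-2.82, SE 0.35), the cold-sensing channel TRPM8 (-2.75, SE 0.44), the Src-family kinase LYN (-2.70, SE 0.42), the Notch coactivator MAML2 (-2.44, SE 0.36) and TRNP1 (-2.3, SE 0.37), with edgeR adjusted p from 0.0134 to 0.0350. For genes that passed in KO C22 and not in KO C28, MID1 among them, neighbouring genes were not examined. A change over a wider region is therefore not told apart from a change of the gene alone. To be named here, genes had to have both Bru-seq libraries of 1 line above both of the other, so that separation adds no support. Apart from AFAP1-AS1 (-10.15, SE 0.73, adjusted p = 0.000332), none of these passed on the Bru-seq libraries alone. The count of 37 became 3 without Bru-seq WT replicate 1, 3 without WT replicate 2, 15 without KO C22 replicate 2, 142 without KO C28 replicate 2, and 4, 5 and 21 without BruUV-seq WT, KO C22 and KO C28.

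Of the gene lists, the immediate early and AP-1 genes, which respond within minutes to growth signals, had the smallest camera p in KO C22. Of 25 members measured in Bru-seq 1 lay above WT, the median log2 fold change was -1.42, and FOS (-5.72, SE 0.95), FOSB (-6.11, SE 1.48) and EGR1 (-3.83, SE 0.98) fell when adjusted over the list alone (camera adjusted p = 1.21e-10; adjusted p = 0.735 with an estimated correlation). Collagens and matrix glycoproteins moved up (33 members, median 0.74, camera adjusted p = 0.00113; adjusted p = 0.735 with an estimated correlation). They were lost with the length offset (0.0592). Adjusted over the list alone 6 of them rose, among them LAMB3 (4.35, SE 0.66), EFEMP1 (3.36, SE 0.78) and FBN1 (3.02, SE 0.74), and COL5A2 fell (-2.90, SE 0.61). Mesenchymal and EMT genes moved up (29 members, median 0.54, camera adjusted p = 0.00193; adjusted p = 0.735 with an estimated correlation), and TCF4, the N-cadherin gene CDH2 and the matrix protein TNC rose by 3.47 (SE 0.92), 2.24 (SE 0.60) and 4.16 (SE 1.11) when adjusted over the list alone. Epithelial genes moved down (29 members, 9 above WT, median -0.70, camera adjusted p = 0.00113; adjusted p = 0.735 with an estimated correlation), with EPCAM at -2.5 (SE 0.92) and the E-cadherin gene CDH1 at -2.69 (SE 1.18). TGF-beta response genes moved up (23 members, 17 above WT, median 0.82, camera adjusted p = 0.00843; adjusted p = 0.798 with an estimated correlation).

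Growth and stress genes moved in KO C22 as well. Mitosis genes (48 members, 43 above WT, median 0.57, camera adjusted p = 5.87e-08) and DNA replication and E2F genes (47 members, 39 above WT, median 0.40, camera adjusted p = 3.65e-06) moved up, both with adjusted p = 0.798 with an estimated correlation. Ribosomal protein genes moved down, with 2 of 73 above WT (median -0.57, camera adjusted p = 2.3e-08; adjusted p = 0.798 with an estimated correlation). So did the unfolded protein and integrated stress response (28 members, 4 above WT, median -0.51, camera adjusted p = 0.000182) and MYC and ribosome biogenesis genes (37 members, 6 above WT, median -0.37, camera adjusted p = 0.00258), both with adjusted p = 0.735 with an estimated correlation. Lower too were hypoxia and glycolysis genes (35 members, 9 above WT, median -0.34, camera adjusted p = 0.0103) and heat shock genes (17 members, 5 above WT, median -0.41, camera adjusted p = 0.0260), both with adjusted p = 0.735 with an estimated correlation. Replication-dependent histones (39 members, 7 above WT, median -0.58, camera adjusted p = 0.00949) and HOX genes, classic Polycomb targets (22 members, 6 above WT, median -0.40, camera adjusted p = 0.00951), moved down with adjusted p = 0.798 with an estimated correlation. NF-kB response genes moved up (22 members, 13 above WT, median 0.28, camera adjusted p = 0.0166; adjusted p = 0.798 with an estimated correlation) and oxidative phosphorylation genes down (46 members, 11 above WT, median -0.28, camera adjusted p = 0.0219; adjusted p = 0.816 with an estimated correlation). No member of any list passed over all genes in Bru-seq, and in the lists of this paragraph 0 members passed when adjusted over the list alone. Of the 18 lists called, leaving out WT replicate 1 lost 11 (adjusted p 0.0563 to 0.829), KO C22 replicate 1 lost 8 (0.101 to 0.958) and KO C22 replicate 2 lost 8 (0.0908 to 0.776). Without WT replicate 2, there were 3 lists lost, HOX and unfolded protein response among them (0.403 to 0.673), and replication and mitosis genes were called the other way (0.0213 and 0.0212). Also lost was 1 list without KO C28 replicate 1 (0.0859) or 2 (0.0768). The immediate early list passed at every omission. Over 12 other settings, HOX and oxidative phosphorylation genes kept their direction in 11 and histones in 10.

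In KO C28, AFAP1-AS1 was again the only gene to pass on the Bru-seq libraries (log2 fold change -10.35, SE 1.10, edgeR adjusted p = 0.0295, n = 2 per line). It gave 1 and 0 reads in Bru-seq and 1 in BruUV-seq, and WT over KO C28 was a ratio of 1423 (95% counting interval 394 to 11752). Unadjusted p below 0.05 was met by 1434 genes, where 1141 would be met without any difference. The count of 1 became 0 without WT replicate 2, KO C28 replicate 1 or KO C28 replicate 2, and 6, 148 and 179 without WT replicate 1, KO C22 replicate 1 and KO C22 replicate 2. DESeq2 called 205 genes and limma-voom 0. With both assays in 1 fit (n = 3 libraries per line) 26 of 20819 genes passed, 17 higher and 9 lower (31 with the length offset, 16 higher and 15 lower, 23 of them among the 26, and 9 after background subtraction, 6 higher and 3 lower). HMCN1 rose by a log2 fold change of 5.65 (SE 0.73), the receptor phosphatase PTPRZ1 by 5.32 (SE 0.85), BTBD11 by 4.44 (SE 0.52), SIPA1L2 by 4.39 (SE 0.63) and the secreted carboxypeptidase CPA4 by 4.26 (SE 0.45). The sialomucin PODXL rose by 4.16 (SE 0.60), the cadherin CDH6 by 4.05 (SE 0.62), SPOCK1 by 3.76 (SE 0.52), LAMB3 by 3.55 (SE 0.44) and MDGA1 by 2.97 (SE 0.38). The formin gene FMN1 (-4.72, SE 0.72), the hyaluronan link protein HAPLN3 (-4.06, SE 0.64), the junction scaffold MPDZ (-3.96, SE 0.43), COL5A2 (-3.25, SE 0.39), the collagen lysyl hydroxylase PLOD2 (-3.04, SE 0.45), the hyaluronan receptor LAYN (-2.98, SE 0.48) and PTPN13 (-2.91, SE 0.36) fell. Their edgeR adjusted p ran from 0.00801 (CPA4, MPDZ) to 0.0420 (PTPRZ1, HAPLN3, LAYN), and AFAP1-AS1 had -10.43 (SE 0.76, adjusted p = 0.000384). The count of 26 became 6 and 1 without WT replicates 1 and 2, 55 without KO C22 replicate 2, 17 without KO C28 replicate 1, 67 without KO C28 replicate 2, and 1, 13 and 1 without BruUV-seq WT, KO C22 and KO C28.

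Antigen presentation genes moved up in KO C28 Bru-seq (17 members, 16 above WT, median 1.32, camera adjusted p = 6.70e-05; adjusted p = 0.756 with an estimated correlation). CIITA, the master activator of MHC class II genes, stood at 4.81 (SE 1.38) and HLA-B at 1.94 (SE 0.88), and 0 members passed when adjusted over the list alone. Interferon response genes moved up (30 members, 21 above WT, median 0.63, camera adjusted p = 0.00186; adjusted p = 0.756 with an estimated correlation), with SAMD9L at 4 (SE 1.14) and IFI44 at 3.12 (SE 1.19). Immediate early genes moved down here too, with 2 of 25 above WT and a median of -1.86 (camera adjusted p = 7.74e-05; adjusted p = 0.756 with an estimated correlation). Adjusted over the list alone 6 fell, among them FOS (-4.38, SE 0.89), FOSB (-6.50, SE 1.53) and EGR1 (-3.25, SE 0.95). YAP and TEAD response genes, read-outs of cell contact and tension, moved down (25 members, 5 above WT, median -0.52, camera adjusted p = 0.00572; adjusted p = 0.756 with an estimated correlation), and ANKRD1 (-7.63, SE 1.46) and AMOTL1 (-3.00, SE 0.83) fell when adjusted over the list alone. The YAP list was lost after background subtraction (adjusted p = 0.103) and without KO C28 replicate 2 (0.0918). In lists that were not called, the endodermal factor GATA6 (-5.06, SE 1.06), WT1 (-3.54, SE 0.76), the cytokine IL18 (-3.90, SE 0.84) and the tight junction gene OCLN (-3.37, SE 0.71) fell and TNFRSF19 rose (3.48, SE 0.84) when adjusted over the list alone. In the collagen and matrix list COL5A2 fell (-3.60, SE 0.63) and LAMB3 rose (3.01, SE 0.63) by that measure.

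Metabolic and growth lists moved in KO C28 Bru-seq with 0 members passing when adjusted over the list alone. Oxidative phosphorylation genes moved up (46 members, 38 above WT, median 0.66, camera adjusted p = 0.000186), as did histones (39 members, 29 above WT, median 0.80, camera adjusted p = 0.00237) and ribosomal protein genes (73 members, 58 above WT, median 0.54, camera adjusted p = 0.00351), each with adjusted p = 0.756 with an estimated correlation. KO C28 replicate 2 lay above replicate 1 by a median log2 of 0.473 in oxidative phosphorylation and 0.766 in ribosomal protein genes, a sign of mature RNA. That cause stays open for this library. Without it oxidative phosphorylation (0.000441) and histones (0.0135) still passed. Mitosis genes (48 members, 42 above WT, median 0.43, camera adjusted p = 0.00228; adjusted p = 0.756 with an estimated correlation) and DNA replication and E2F genes (47 members, 29 above WT, median 0.16, camera adjusted p = 0.0251; adjusted p = 0.760 with an estimated correlation) moved up. The unfolded protein and integrated stress response (28 members, 10 above WT, median -0.78, camera adjusted p = 0.00703) and cholesterol synthesis (23 members, 4 above WT, median -0.70, camera adjusted p = 0.0251) moved down, both with adjusted p = 0.756 with an estimated correlation. Mesenchymal and EMT genes (29 members, 17 above WT, median 0.81, camera adjusted p = 0.0475), acinar and islet markers (7 members, 7 above WT, median 1.47, camera adjusted p = 0.0349) and basal-like subtype genes (11 members, 9 above WT, median 1.05, camera adjusted p = 0.0494) moved up, each with adjusted p = 0.756 with an estimated correlation. Without the shallow KO C28 replicate 2 the adjusted p was 0.137 for ribosomal proteins, 0.363 for EMT, 0.0918 for YAP, 0.819 for acinar and islet markers and 0.384 for the basal-like list, while epithelial genes passed as lower (0.0135; 0.967 with all libraries). Of the 15 lists called, leaving out WT replicate 1 lost 4 (adjusted p 0.116 to 0.568), WT replicate 2 lost 8 (0.0820 to 0.987) and KO C28 replicate 1 lost 11 (0.0523 to 0.990). Leaving out KO C22 replicate 1 lost 4 (0.0580 to 0.100) and KO C22 replicate 2 lost 3 (0.104 to 0.125), and without WT replicate 2 replication and mitosis genes were called the other way (0.00469 and 0.0131). Antigen presentation passed at every omission.

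**Figure D2:**
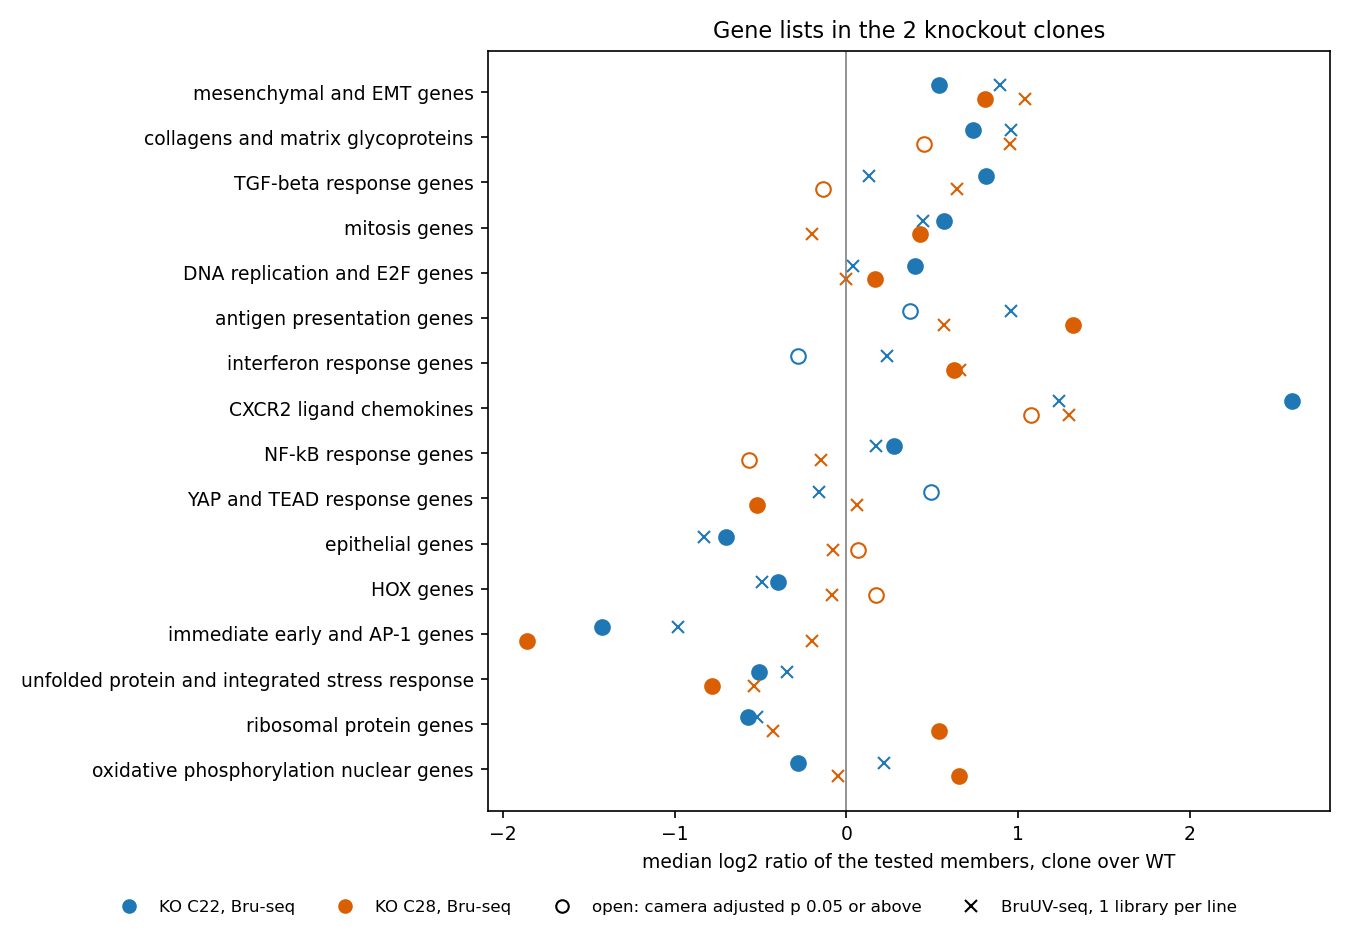
Median log2 fold change of 16 gene lists in each clone against WT. Filled points have camera adjusted p below 0.05, open points 0.05 or above, and crosses are BruUV-seq.

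Some genes changed the same way in both clones. With both assays in 1 fit, 10 genes passed in each clone with the same sign, where 0.0212 higher and 0.00476 lower would be met if the clones were independent. HMCN1, LAMB3, SIPA1L2, ADAMTS6, SPOCK1 and CPA4 rose in KO C22 and KO C28, and COL5A2, AFAP1-AS1, PTPN13 and MAGI2-AS3 fell. SPOCK1 stood at 20.1 (SD 2.88), 493 (SD 71.2) and 322 (SD 189) CPM in Bru-seq of WT, KO C22 and KO C28, and COL5A2 at 204 (SD 39.9), 26.7 (SD 9.04) and 19.2 (SD 4.12), with n = 2 libraries per line. The metalloprotease gene ADAMTS6 rose by 4.12 (SE 0.40, edgeR adjusted p = 0.00253) and 2.88 (SE 0.38, adjusted p = 0.0151), and CPA4 by 3.48 (SE 0.44, adjusted p = 0.0134) in KO C22 and 4.26 (SE 0.45, adjusted p = 0.00801) in KO C28. The count of 10 became 35 without Bru-seq KO C28 replicate 2, 1 without WT replicate 1, 1 without WT replicate 2, and 1, 4 and 1 without BruUV-seq WT, KO C22 and KO C28. The clones share their WT libraries, so part of the overlap arises from the design. Simulated clones that share the WT libraries and nothing else gave 0 such genes in each of 20 runs, a correlation across genes of 0.493 between the clones' fold changes where 0.650 was measured, and a covariance 0.448 lower than measured. On Bru-seq alone 1 gene (AFAP1-AS1) passed in both clones and simulation gave 0.05 per run, with a correlation of 0.485 where 0.658 was measured. On that same Bru-seq fit, genes with unadjusted p below 0.05 in both clones the same way numbered 205 where simulation gave 228, and 64.7% of genes had the same sign where simulation gave 66.7%, so neither exceeded the simulated level. With both assays they did, at 504 genes where simulation gave 183 and 67.9% where it gave 66.7%. WT holds 2 Bru-seq libraries, too few to give each clone its own WT pair, so part of the excess may still come from shared controls. Folds that share no library, KO C22 in Bru-seq and KO C28 in BruUV-seq each against the WT library of that assay, correlated across 11811 genes at 0.43, and KO C28 in Bru-seq with KO C22 in BruUV-seq at 0.55 (0.36 without KO C28 replicate 2). Over the same 11811 genes the clones' log2 ratios within Bru-seq, which share WT libraries, correlated at only 0.38. That is below the 0.658 of all tested genes in the Bru-seq fit, which was taken from edgeR fold changes and not from ratios of CPM. Measure and genes both differ between these correlations, and simulation was not run on this subset. Over these 11811 genes the same clone in Bru-seq and BruUV-seq correlated at 0.58 (KO C22) and 0.61 (KO C28). Within BruUV-seq, where the clones share 1 WT library, the ratios correlated at 0.61.

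**Figure D3:**
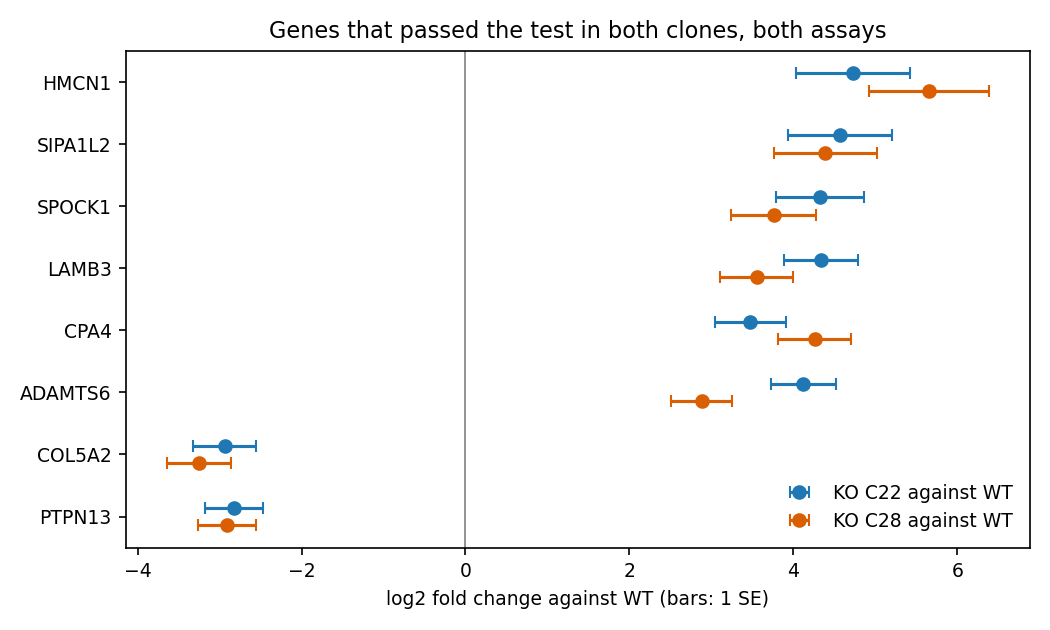
Log2 fold change with 1 standard error in KO C22 and KO C28 for 8 genes that passed in both clones with both assays in 1 fit.

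Genes around AFAP1-AS1 had far smaller fold changes than the transcript. AFAP1 itself, on the opposite strand, stood at -0.39 (SE 0.60) in KO C22 and -0.98 (SE 0.61) in KO C28 with both assays in 1 fit. The 13 tested genes within 1 Mb, AFAP1 included, had median log2 fold changes of -0.30 and -0.45, and the lowest of them, SH3TC1, lay at -2.89 in KO C22 (edgeR adjusted p = 0.487).

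**Figure D4:**
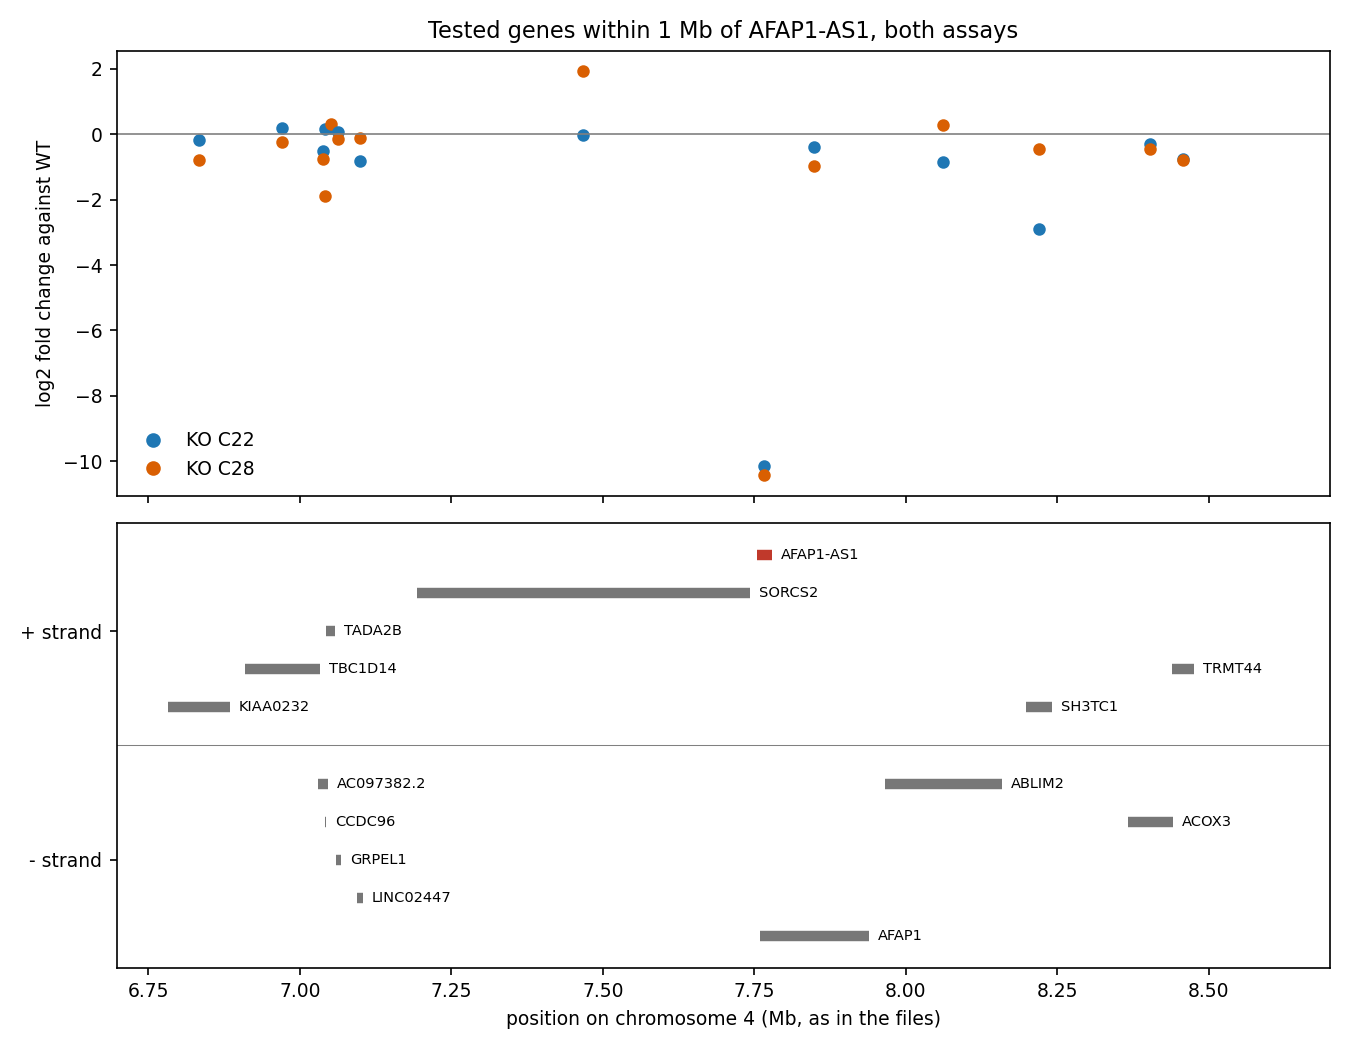
Log2 fold change against WT of the genes tested within 1 Mb of AFAP1-AS1 in both clones, with their positions and strands.

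The clones also differed from each other. No gene passed between KO C28 and KO C22 in edgeR, on Bru-seq (smallest adjusted p 0.959, n = 2 per clone) or with both assays (smallest 0.0539, n = 3). The nearest was GJA1, lower in KO C22 and at 1.47 (SE 0.51) against WT in KO C28, a difference of 5.22 (SE 0.61). Unadjusted p below 0.05 was met by 747 genes in Bru-seq and 1189 with both assays, and DESeq2 called 53 and 228. The Bru-seq count of 0 became 186 without KO C22 replicate 1 and 1 without KO C22 replicate 2. With both assays it became 18 without KO C28 replicate 2. Camera called 12 lists on Bru-seq, each with adjusted p = 0.78 with an estimated correlation. Higher in KO C28 were ribosomal proteins (median difference 1.22, camera adjusted p = 1.96e-12), oxidative phosphorylation (0.93, 1.98e-08), histones (1.47, 1.35e-07), interferon response (1.21, 5.93e-06), antigen presentation (1.06, 0.000695), basal-like (1.35, 0.0157), epithelial (1.51, 0.0320), developmental factors (0.53, 0.0320), heat shock (0.80, 0.0320) and HOX genes (0.33, 0.0321). YAP (-1.33, 1.16e-05) and NF-kB responses (-0.73, 0.00254) were lower. Adjusted over the list alone, ANKRD1 (-6.74, SE 1.42), GATA6 (-6.06, SE 1.10), EFEMP1 (-5.60, SE 0.88), CDH2 (-2.56), WT1 (-3.67), TGFB2 (-3.63), IL18 (-3.46) and the epithelial gene OCLN (-2.75) were among those lower in KO C28, and SPARC (4.73), the epithelial gene KRT19 (3.21) and AGR2 (2.85) were higher. Of the 12 lists, 5 were lost without WT replicate 1 (adjusted p 0.0589 to 0.149), 4 without WT replicate 2 (0.0974 to 0.161), 6 without KO C22 replicate 1 (0.0511 to 0.958), 3 without KO C22 replicate 2 (0.305 to 0.987), 4 without KO C28 replicate 1 (0.0637 to 0.197) and 5 without KO C28 replicate 2 (0.116 to 0.723). Ribosomal protein, oxidative phosphorylation, histone, antigen presentation and YAP lists passed at every omission. In BruUV-seq (1 library per line) only ribosomal proteins of these kept the order of the clones, with medians of -0.52 in KO C22 and -0.43 in KO C28. The order turned for histones (0.62 and -0.12), oxidative phosphorylation (0.22 and -0.05), antigen presentation (0.96 and 0.57) and YAP genes (-0.16 and 0.06). HOX genes kept their direction between clones in 11 of 12 other Bru-seq settings.

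The series asks about the CXCL1-CXCR2 axis, through which tumour cells draw in neutrophils. CXCL1 (chromosome 4, 73869404 to 73871242, plus strand) stood at 5.11 and 2.32 CPM in WT Bru-seq, 31.3 and 3.98 in KO C22, 9.50 and 23.8 in KO C28, and 4.12, 9.88 and 9.99 in BruUV-seq of WT, KO C22 and KO C28. Its log2 fold change was 2.36 (SE 1.03) in KO C22 and 1.90 (SE 1.01) in KO C28 with n = 2 per line, and it did not pass (edgeR unadjusted p of 0.0420 and 0.0869, adjusted p of 1 and 0.728). With both assays in 1 fit it was 2.04 (SE 0.76, adjusted p = 0.666) and 1.78 (SE 0.75, adjusted p = 0.473), and CXCL1 was called in 0 of 19 alternative Bru-seq analyses. These gave a log2 fold change of 0.07 to 3.19 in KO C22, the lowest without KO C22 replicate 1, and 1.37 to 2.56 in KO C28. CXCL2 lay at 2.83 (SE 1.70) and 0.25 (SE 1.61), with 0 reads in KO C28 replicate 2, CXCL3 at 3.32 (SE 2.49) and 2.06 (SE 2.41) from 0 to 39 reads, and CXCL8 at 1.22 (SE 1.03) and -1.71 (SE 1.06). CXCL8 was 2.81 and 17.1 CPM in WT Bru-seq, 36.0 and 6.49 in KO C22 and 2.39 and 4.68 in KO C28. Between the clones with both assays the difference in CXCL8, KO C28 minus KO C22, was -2.42 (SE 0.83). It did not pass over all genes (edgeR adjusted p = 0.735). Over the 3 tested members of the list alone its edgeR adjusted p was 0.0406, without adjustment for the number of lists. CXCL5 and CXCL6 had at most 10 reads in a library and PPBP had 0, so these were not tested. As a list the ligands moved up in KO C22 (4 members, 4 above WT, median 2.59, camera adjusted p = 0.00949; adjusted p = 0.735 with an estimated correlation) and not in KO C28 (3 above WT, median 1.08, camera adjusted p = 0.827), and the difference between the clones was not called (camera adjusted p = 0.167). The KO C22 call rests on few libraries, for camera adjusted p was 0.170 without WT replicate 1 and 0.630 without KO C22 replicate 1. With both assays it was 0.0242, and 0.193 without KO C22 replicate 1, and the list was not called with an estimated correlation. Neutrophil markers gave camera adjusted p = 0.715 in KO C22 and 0.232 in KO C28 (4 members). PADI4, whose enzyme drives neutrophil extracellular traps, lay at 3.88 (SE 1.87) in KO C28.

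BruUV-seq against Bru-seq shows where signal moved after UV. With clone as a covariate, 93 genes passed in edgeR (89 higher, 4 lower, n = 3 BruUV-seq and 6 Bru-seq libraries, smallest adjusted p 0.0154). The immediate early genes IER2 (3.45, SE 0.36) and JUNB (2.98, SE 0.53), SMIM29 (3.10, SE 0.49), ABHD17A (3.05, SE 0.46) and the vascular peptide gene ADM (2.96, SE 0.38) were higher, and FLJ46284 (-2.74, SE 0.50) and the long neuronal gene NAV3 (-1.76, SE 0.32) lower. The 93 became 3470 (2144 higher, 1326 lower) without Bru-seq KO C28 replicate 2, 45 without WT replicate 2, and 0 or 1 at any other omission. RLE factors gave 1 gene, and library totals alone, the filter at 100 counts, background subtraction or the length offset gave 0. DESeq2 called 3941, 1672 higher and 2269 lower. Another choice of 3 libraries with 1 per line gave 1230 genes, so chance is not excluded for the 93. Short genes gained and long genes lost. The median log2 ratio fell from 0.62 in WT genes under 5 kb to -0.91 above 200 kb, from 0.57 to -1.17 in KO C22 and from 0.83 to -1.26 in KO C28 (0.46 to -0.94 with KO C28 replicate 1 alone). Across 20819 genes the rank correlation of ratio with length was -0.47, -0.42 and -0.39.

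**Figure D5:**
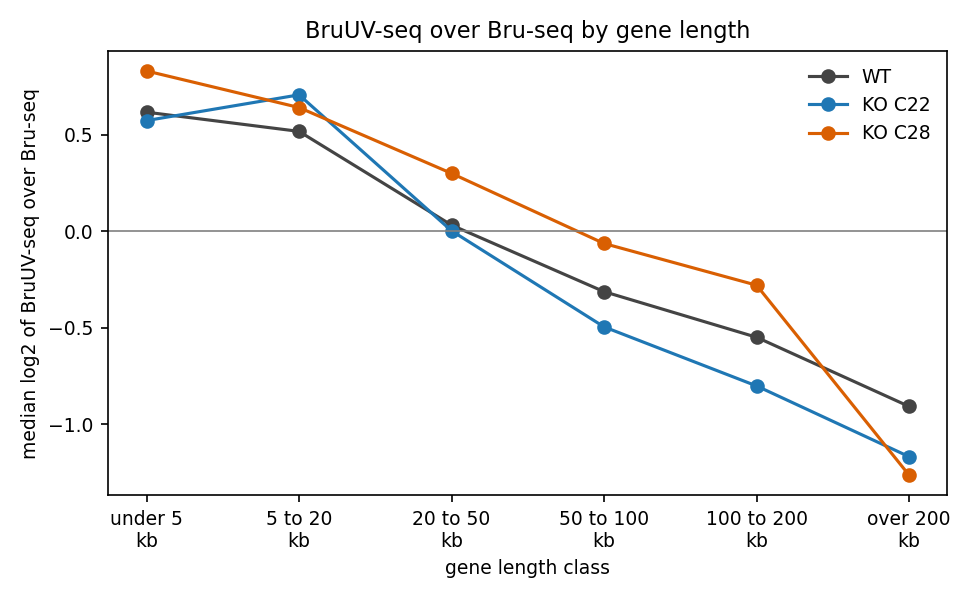
Median log2 ratio of BruUV-seq to Bru-seq by gene length in WT, KO C22 and KO C28.

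Between lines BruUV-seq has 1 library each, so the values below carry no p. SPOCK1 stood at 21.8, 256 and 212 CPM in WT, KO C22 and KO C28, LAMB3 at 2.76, 50.2 and 51.5, COL5A2 at 107, 12.1 and 14.5, and PTPN13 at 58.0, 8.69 and 9.99. The log2 ratios of CXCL1 were 1.24 and 1.30 in KO C22 and KO C28, of CXCL2 2.55 and 2.5, and of CXCL8 1.19 and -0.41. Of genes with Bru-seq unadjusted p below 0.05, 434 of 458 in KO C22 (94.8%) and 1203 of 1434 in KO C28 (83.9%) kept their direction in BruUV-seq, where 59.5% and 66.5% of all genes did. Medians of gene lists were placed among 10000 random lists. Both clones are set against the same WT library, so an extreme value in both does not count as 2 separate findings. A percentile ranks a list against other genes of the same libraries and does not measure the spread between libraries. For KO C22 and KO C28 these percentiles were 100 and 100 for EMT genes (medians 0.90 and 1.04), 100 and 100 for collagens and matrix (0.96 and 0.95), 99.99 and 99.6 for antigen presentation, 94.5 and 99.99 for interferon response, and 84.6 and 100 for TGF-beta response. CXCR2 ligands (3 members) were at 97.4 and 98.1. Ribosomal proteins were at 0 and 0 (medians -0.52 and -0.43), the unfolded protein response at 2.59 and 0, and immediate early genes at 0 and 11.4 (medians -0.98 and -0.20). Mitosis genes were at 100 and 8.90, histones at 100 and 18.6, heat shock at 99.98 and 97.3, HOX at 1.21 and 39.5, epithelial genes at 0.01 and 29.9, and basal-like genes at 23.5 and 99.7. Some lists called on Bru-seq had BruUV-seq medians of the opposite sign. In KO C22, lower in Bru-seq, these were MYC genes (median 0.28, percentile 99.4), oxidative phosphorylation (0.22, 99.2), histones (median 0.62), heat shock (0.89) and hypoxia genes (0.10, percentile 86.2). In KO C28, higher in Bru-seq, they were ribosomal proteins, mitosis genes (-0.20), histones (-0.12), oxidative phosphorylation (-0.05, percentile 57.5) and replication genes (-0.00137, percentile 82.3), and YAP genes, lower in Bru-seq, had 0.06 (percentile 83.9).

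The remaining lists were not called on Bru-seq in the clones named, with camera adjusted p given for KO C22 and then KO C28. Chromatin lists gave, for KDM6 and COMPASS-like members, 0.768 and 0.579 (11 members), for the Polycomb complex PRC2 0.669 and 0.605 (11), and for PRC1 0.186 and 0.472 (19), with PRC1 at percentile 2.43 of random lists in KO C22 BruUV-seq and 19.6 in KO C28. Developmental factors outside HOX gave 0.698 and 0.0787 (53, medians 0.10 and 0.63). With both assays they were called up in KO C28 (median 0.57, camera adjusted p = 0.0128; adjusted p = 0.793 with an estimated correlation), and lost without Bru-seq KO C28 replicate 2 (0.255) or BruUV-seq KO C28 (0.0609). Cell identity lists gave 0.969 and 0.472 for pancreatic factors (15) and 0.516 and 0.326 for the classical subtype (9), in which AGR2 fell in KO C22 (-3.66, SE 0.69) when adjusted over the list alone. Signalling lists gave 0.669 and 0.647 for other chemokines (16), 0.768 and 0.917 for WNT and NOTCH (27) and 0.507 and 0.151 for p53 (28). Markers of other cells gave 0.554 and 0.204 for macrophages and lymphocytes (7) and 0.604 and 0.134 for fibroblasts and endothelium (9). The fibroblast and endothelial markers were called up in KO C28 with both assays (median 1.05, camera adjusted p = 0.0369; adjusted p = 0.793 with an estimated correlation), lost without Bru-seq KO C28 replicate 2 (0.399) or BruUV-seq KO C28 (0.0823), and lay at percentiles 97.4 and 99.3 in BruUV-seq. Lists called in 1 clone gave, in KO C22, 0.0867 for antigen presentation, 0.318 for interferon, 0.0828 for YAP, 0.0962 for cholesterol, 0.715 for acinar and islet and 0.640 for basal-like genes. With both assays antigen presentation was called up in KO C22 too (median 0.75, camera adjusted p = 0.000994; adjusted p = 0.725 with an estimated correlation). It was lost there without BruUV-seq KO C22 (0.242). In KO C28 they gave 0.15 for NF-kB, 0.614 for HOX, 0.967 for epithelial, 0.389 for collagens, 0.877 for TGF-beta, 0.313 for hypoxia, 0.472 for heat shock and 0.326 for MYC. With both assays in 1 fit camera called 14 lists in KO C22 (adjusted p = 0.725 with an estimated correlation) and 15 in KO C28 (adjusted p = 0.793 with an estimated correlation), among them EMT genes in both (1.30e-05 and 0.000883), which passed at every omission. Without WT replicate 2, 6 lists were lost in KO C22 (0.0653 to 0.927) and 8 in KO C28 (0.0693 to 0.997), and 5 were lost in KO C22 without KO C22 replicate 1 (0.0761 to 0.193). In KO C28, 7 were lost without KO C28 replicate 1 (0.0634 to 0.819), 6 without KO C28 replicate 2 (0.121 to 0.692) and 4 without BruUV-seq KO C28 (0.0609 to 0.0857), and other omissions lost 0 to 3 in either clone. In that fit, adjusted over the list alone, TNC (4.60 and 3.97), TCF4 (3.31 and 3.16) and WNT5A (2.38 and 2.91) rose in KO C22 and KO C28. Over all genes none of them passed (edgeR adjusted p from 0.0613 to 0.236). The rotation test fry called 0 lists.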

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

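The comparison between clones and the shares of reads outside genes were planned, and the tests on Bru-seq KO C28 replicate 2 were chosen after it was seen to stand apart. In 12 gene lists the clones' responses differed from each other by the camera test of the difference itself on Bru-seq. Adjusted p was 1.96e-12 for ribosomal proteins, 1.98e-08 for oxidative phosphorylation, 1.35e-07 for histones, 5.93e-06 for interferon response, 1.16e-05 for YAP and TEAD response, 0.000695 for antigen presentation, 0.00254 for NF-kB response, 0.0157 for basal-like genes, 0.0320 for epithelial genes, developmental factors and heat shock genes, and 0.0321 for HOX genes. With an estimated correlation adjusted p was 0.78 for each. Without Bru-seq KO C28 replicate 2, 5 of the 12 were lost (adjusted p 0.116 to 0.723). In BruUV-seq the ribosomal protein median was below WT in both clones (-0.52 in KO C22 and -0.43 in KO C28), where Bru-seq had -0.57 and 0.54. YAP and TEAD genes, -0.52 in KO C28 Bru-seq, had a BruUV-seq median of 0.06, above the -0.16 of KO C22. Histone, oxidative phosphorylation, antigen presentation and heat shock medians also had the opposite order between the clones in BruUV-seq. Those of the other lists kept the Bru-seq order.

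The reads outside the counted genes, which no comparison uses, made up 20.01% of Bru-seq KO C22 replicate 1 and 46.5% of Bru-seq KO C28 replicate 2, above the 13.6% and 14% of the WT libraries. The other Bru-seq libraries of these clones had 10.8% and 14.1%, and BruUV-seq 9.93% to 12.6%.

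Bru-seq KO C28 replicate 2 correlated with KO C28 replicate 1 across genes at 0.755, while WT replicate 1 and KO C28 replicate 1 reached 0.954. Shallow sequencing is argued against, since KO C28 replicate 1 and WT replicate 1 thinned to its depth still correlated at 0.959. Evenly spread background such as genomic DNA stays open. Reads in olfactory receptor genes were 3.51 times as dense as in the next densest Bru-seq library, KO C22 replicate 1, between the bounds of 1.5 and 5 set for the test. Subtracting that density from every gene brought the correlation with replicate 1 to 0.777 (0.740 before), with 20.1% of its gene reads removed. Over 0.85 was expected if this were the cause and under 0.78 if not. By these bounds as first set, 0.777 counts narrowly against background as the cause. The 95% interval across genes, 0.771 to 0.782, spans 0.78. Genes are not replicates, so that interval does not measure the spread between libraries. Other values, for which no bounds were set, go with such background. The antisense KCNMA1-AS1 had 6.05% of the read density of KCNMA1 here, against 0.0261% to 0.852% in the other Bru-seq libraries. Against the mean of all libraries the median log2 was 1.56 for genes over 200 kb and -0.81 under 5 kb. Between these classes it did not rise with length, at -0.05 for 5 to 20 kb, -0.38 for 20 to 50 kb, -0.40 for 50 to 100 kb and -0.35 for 100 to 200 kb. Carry-over of mature RNA stays open as well, because ribosomal protein and oxidative phosphorylation genes lay a median log2 of 0.687 above replicate 1 (quartiles -0.07 and 1.23), between the bounds of 0.5 and 1. The rule for the subtraction was changed after its value was seen, to ask that the whole interval lie past a bound. Without that change the value would have counted against background. No biological explanation was tested, since both replicates carry the same label.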

How the results depend on the processing

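The fit of both assays, background subtraction, the length offset and quality weights were chosen after the data were seen. Causes were not tested except where a setting tests fewer genes or libraries. AFAP1-AS1 was called in all 22 alternatives of the fit with both assays in each clone and in 11 of 19 (KO C22) and 10 of 19 (KO C28) on Bru-seq. The 41 pairs of gene and comparison named because they passed with both assays kept their direction throughout, and were called in 10 to 22 alternatives. The rule for naming genes already asked for Bru-seq libraries that do not overlap between groups. A kept direction therefore adds no support.

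On Bru-seq the count of 1 in KO C22 became 2 with RLE or without the top 20 genes, 0 with library totals alone, limma-voom, background subtraction or adjusted p below 0.01, 91 with DESeq2, 43 with no filter and 14 with quality weights. The count of 1 in KO C28 became 205 with DESeq2, 190 with no filter, and 0 with library totals, voom, the filter at 100 counts, background subtraction, quality weights or adjusted p below 0.01. In both clones 1 became 32 with DESeq2, 21 with no filter, and 0 under those same other settings. Between clones 0 became 53 with DESeq2 and 12 with no filter. With replicate number as a block the counts in KO C22, KO C28 and both clones were 0, though the numbers do not pair the libraries (residual correlations 0.435, -0.003 and -0.479).

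With both assays the 37 in KO C22, 26 in KO C28 and 10 in both clones became 348, 711 and 164 with DESeq2, 272, 1100 and 137 with no filter, 56, 47 and 24 with the filter at 100 counts, 6, 9 and 3 after background subtraction, 398, 358 and 151 with quality weights, and 4, 4 and 1 at adjusted p below 0.01. A block on replicate number gave 49 in KO C28 and 19 in both clones. Between clones 0 became 228 with DESeq2, 230 with no filter, 2 after background subtraction, 2 with the length offset and 100 with quality weights.

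BruUV-seq against Bru-seq, 93, became 1 with RLE, 0 with library totals, the filter at 100 counts, background subtraction or the length offset, 3941 with DESeq2 (1672 higher, 2269 lower), 2326 with no filter, 158 without the line covariate, and 8944 with quality weights (5025 higher, 3919 lower). Keeping only replicate 1 of each line, in place of the block, gave 8192 (4228 higher, 3964 lower).

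Leaving out 1 library gave 0 to 22 genes in KO C22, 0 to 179 in KO C28, 0 to 186 between clones and 0 to 5 in both clones on Bru-seq. With both assays it gave 3 to 142, 1 to 67, 0 to 18 and 1 to 35, and for BruUV-seq against Bru-seq 0 to 3470. A line left with 1 library is then assumed to vary like the others.

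KDM6A in KO C22 was -0.42 with the length offset and -0.13 to 0.52 on leaving out a library, and in KO C28 -2.32 to 0.12. CXCL1 in KO C22 was 0.07 without KO C22 replicate 1. CXCL2 in KO C28 was -1.14 with voom, -1.25 with quality weights, -1.62 with the replicate block, -0.06 without WT replicate 1 and -7.32 to 1.16 over omissions. CXCL3 in KO C28 was -4.10 to 6.02, CXCL8 in KO C22 -0.65 to 3.02 and CXCL8 in KO C28 -2.53 to 0.0834 over omissions.

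For gene lists an estimated correlation and fry called 0 in each comparison and fit. On Bru-seq, background subtraction lost HOX, heat shock, histone and oxidative phosphorylation lists in KO C22 (adjusted p 0.0689 to 0.272), basal-like, EMT, YAP, cholesterol and unfolded protein lists in KO C28 (0.0655 to 0.709), and NF-kB, basal-like and epithelial lists between clones (0.0809 to 0.241); acinar and islet markers were then not tested in KO C28. The length offset lost, among others, collagen, HOX, heat shock, histone and oxidative phosphorylation lists in KO C22 (0.0592 to 0.426), basal-like, EMT and replication lists in KO C28 (0.102 to 0.185), and HOX, developmental, epithelial and heat shock lists between clones (0.0577 to 0.114). In KO C28 with both assays 15 became 9 after background subtraction and 7 with quality weights. Leaving out 1 library gave 9 to 17 in KO C22, 7 to 12 in KO C28 and 9 to 12 between clones on Bru-seq, and 9 to 18, 10 to 17 and 10 to 15 with both assays. The share of Bru-seq genes with the same direction in BruUV-seq was 98.2% in KO C22 and 93.8% in KO C28 with the filter at 100 counts, 79.4% in KO C28 with RLE and with library totals, and 93.1% and 92.7% without KO C28 replicate 2. The rank correlation with length was -0.52, -0.56 and -0.24 in WT, KO C22 and KO C28 with the filter at 100 counts, and -0.41 in KO C28 with a prior count of 0.5. At the depth and spread of these libraries, the tests on simulated counts found at most 1.33% of 2-fold changes.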

Other observations

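The values of this paragraph come from the fit of both assays, which was added after the data were seen. In KO C28 the integrated stress genes CHAC1, PSAT1, SESN2, TRIB3, SLC7A11 and HERPUD1 fell when adjusted over the list alone (CHAC1 and TRIB3 in KO C22 too), and SAMD9L (3.76), IFI44 (3.14), INHBA (3.34) and PADI4 (3.45, SE 1.20) rose by the same measure. PADI4 had edgeR adjusted p = 0.0445 over the neutrophil list alone and 0.457 over all genes. The matrix gene SPARC fell in KO C22 (-3.44) and the metalloprotease genes MMP14 (2.77, KO C22) and MMP2 (2.10, KO C28) rose when adjusted over the list alone. Over all genes SPARC, MMP14 and MMP2 did not pass (edgeR adjusted p of 0.149, 0.171 and 0.336).

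The tests of chromosome regions were chosen after the genes were seen, and the condition on the lowest neighbour of AFAP1-AS1 was added after its value. Genes that changed in both clones could sit in regions lost or gained when the clones were grown from single cells. For the 10 genes as a set this is argued against: for 0% of them did the neighbours within 1 Mb move the same way by 50% of the change or more in both clones, and around AFAP1-AS1 the lower of the clones' neighbour medians was -0.45, where the transcript itself had log2 fold changes of -10.15 and -10.43. For LAMB3 a change over the whole region stays open, since the medians of its 9 neighbours were 2.12 in KO C22, 48.8% of the fold change of LAMB3, and 3.27 in KO C28, where LAMB3 had 3.55. For AFAP1-AS1 a deletion confined to the transcript or its promoter stays open, and so does silencing shared by the clones, neither of which counts over gene bodies can tell apart. Whether loss of KDM6A function, growth from single cells or passage since the WT line was sampled lies behind the shared changes was not tested, since no clone with intact KDM6A was sampled. Of 100 regroupings of the 9 libraries into 3 sets of 3, only the real one gave 10 or more such genes (highest other 0). Among the 36 with 1 BruUV-seq library per set it was again 1 (highest other 0). Regroupings that mix lines put the differences between lines into the spread, which by itself leaves few genes to pass. These counts show that libraries of a line resemble each other, and they cannot exclude chance differences between single lines.

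Chromosome X had lower signal in KO C22, a pattern seen in the data before it was tested. Its median log2 fold change was -0.57 in Bru-seq and -0.30 in BruUV-seq, against -0.11 and -0.07 for the autosomes together. It was not alone: chromosome 10 had -0.38 and -0.37, lower than chromosome X in BruUV-seq, and chromosome 17 had -0.44 and -0.22. Loss of a whole copy of chromosome X would be a candidate explanation, but 62.5% of the 8 bins of 20 Mb lay below -0.2 in both assays, short of the 80% set for it and above the 50% that would argue against it. The bin at the start of the chromosome (39 genes) had -1.06 and -1.17, and was low in KO C28 too (-0.87 and -0.36, where the autosomes had -0.52 and -0.07), and the bin at its end had -0.50 in Bru-seq and 0.40 in BruUV-seq. Partial loss, whole loss and altered transcription cannot be told apart from these medians, and KDM6A lies on this chromosome at a log2 fold change of 0.24 (SE 0.85).

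Other splits of the libraries were counted as planned, and those restricted to 1 library per line or 1 BruUV-seq library per set were chosen after the counts were seen. For KO C22 against WT with both assays the real split gave 37 genes and the highest other 0, and for KO C28 26 and 0. With 10 splits each, with 1 as large as the real one, the share cannot fall below 0.1. For BruUV-seq against Bru-seq, 2 of the 81 choices of 3 libraries that gave an estimate had as many genes as the real 93. The highest other gave 1230, for Bru-seq WT replicate 1, KO C22 replicate 1 and KO C28 replicate 2 together. The real choice takes 1 library per line, and so does that one, so among the 27 choices of that kind 2 reach 93 and chance cannot be excluded for this count. The larger count points to a structure of the samples that was not tested. Those libraries are the ones with the denser reads in olfactory receptor genes among the Bru-seq libraries of their line (0.00754 against 0.00413, 0.0246 against 0.00305 and 0.0865 against 0.00873 reads per kb and M reads).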
